A study of Mus musculus with 6 samples.

How the data were processed

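Poly(A) RNA from 4T1 cells was sequenced on an Illumina NovaSeq instrument with paired-end reads, per the labels' protocols. The series holds 3 DAP and 3 control libraries, which carry the same batch label. Each library has its own table, and the deposited values are in FPKM, per the file headers. The aligner, the counting tool and the genome build are not given in the sources used here. Identifiers begin with the prefix of the BALB/cJ strain annotation for 40303 loci, and 718 others mark loci added to it. None of the 41021 identifiers matched an entry in the symbol tables used here, so 35 gene lists fixed before the data were examined, and the genes that were to be named in any case, could not be tested. The mouse reference genome at hand carries another annotation and was not used here.

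FPKM divides a count by gene length and by a library divisor. Whole counts, lengths and library divisors were searched for jointly so that every value was met within the rounding of its 6 decimals. All 23485 genes with a value above 0 came out whole. A gene's counts are fixed only up to a common factor, and the smallest whole counts that met its values were taken. In simulated tables of 23485 genes, counts were recovered exactly for 99.3% of genes above 0 in all libraries, and in the right ratio for 100% of them. Over genes above 0 in any library the share recovered exactly was 98.9%. The simulated counts were Poisson draws around the recovered means, without the excess of even counts described in the closing section. These shares therefore need not hold for the deposited values, above all for genes seen in few libraries. The divisors found were equal to median-of-ratios size factors of the recovered counts, up to a common factor, in 6 of 6 libraries within a relative tolerance of 1e-06. The deposited FPKM therefore already held a scaling between libraries of that kind, which is a measurement on the values and is stated by no label. Recovered totals ran from 33847698 to 37911033 counts per library and give the depth behind the values.

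The plan fixed before the data were examined assumed counts and gave a fallback for normalized values, which was used because the tables hold FPKM. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with the group as the only term, over all genes with a value above 0 in at least 1 library. P-values are two-sided and were adjusted by Benjamini-Hochberg over 23485 genes, with a threshold of 0.05. A gene could be named if its adjusted p was under 0.05, its mean reached 5 FPKM in either group, all libraries of 1 group lay above all of the other, and it was not an added locus. The plan stated this minimum in CPM and left out predicted genes by symbol, which could not be applied. It would have named 8 genes in each direction. Since identifiers have no names here, the 2 with the largest rise and the 2 with the largest fall in log2 fold change are given.

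The limma step was tested on simulated counts turned into FPKM, with 200 genes of mean FPKM 1 or more changed. The noise was first set to the mean variance in each abundance bin. With 22687 genes, 28% of 100 genes changed by 0.5 on the log2 scale and 74% of 100 changed by 1 were called, and 7 of 109 calls were unchanged genes (6.42%). A second noise setting, the median variance in each bin, was added after that result was seen. With 22576 genes it gave 49% and 74%, and 11 of 134 calls were unchanged genes (8.21%). In both settings at least 98% of changed genes had the right sign. The share of false calls lay above the 5% that the threshold aims at in both, on few calls. Only 200 genes were changed here, while 33.6% of genes were called in the data, so these shares need not carry over to those calls.

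Libraries were compared for duplicates by the median over genes of the chi-square of 2 libraries' recovered counts, divided by that of sampling noise. Pairs within a group gave 4.12 to 8.12 for genes with 100 counts or more, so no library was a copy of another. Pairs between groups gave 57.1 to 62.2. Shares of counts were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3 libraries.

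The alternatives run were library size only, upper-quartile and median-of-ratios scaling, a pseudocount of 0.1, a mean FPKM of 1 or more, a CPM of 1 or more in 3 libraries, and limma-voom on the recovered counts. Further ones were the replicate number as a block, a test against a 1.2-fold change (treat), and each library left out in turn. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the recovery and the plots.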

Results

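RNA was sequenced from 4T1 cells, a mammary carcinoma line from BALB/c mice that is widely used as a model of triple-negative breast cancer. The labels describe 2 groups of 3 libraries. Cells of the DAP group received DAP at 1.62 mg/mL and were collected at 24 h according to the labels, although the protocol speaks of incubation overnight, and per the protocol in the labels cells of the control group had medium without it. DAP stands for deer antler peptides in the series title, which also names a pH-responsive carrier loaded with them. The column headings of the deposited tables call the libraries of the DAP group CS_HA_DAP and those of the control group D. What D stands for is not stated. Whether the DAP group received the free peptides or the loaded carrier is therefore not settled by the sources used here, nor is it excluded that the control group itself received free DAP, in which case every value of DAP over control would compare 2 preparations. The groups below follow the labels. The title places the series in the context of DNA damage stress and checkpoint imbalance.

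The tables list FPKM for 41021 identifiers, of which 40303 belong to the BALB/cJ strain annotation and 718 mark loci added to it. The files do not pair the identifiers with gene names, and none matched a symbol in the tables used here, so genes are given by identifier and no pathway was tested. Whole numbers that met the FPKM were found for all 23485 genes with a value above 0 in any library. The smallest such numbers were taken as recovered counts, and for genes seen in few libraries the true counts may be higher. The recovered counts summed to 37911033, 35387029 and 33847698 in DAP replicates 1, 2 and 3, and to 35674979, 33865250 and 35753815 in control replicates 1, 2 and 3. Between 19351 and 19651 genes had a value above 0 in a given library. The libraries of a group were alike, with Pearson's r of log2(FPKM + 1) across 12065 genes between 0.991 and 0.993 within groups and between 0.952 and 0.953 between groups. Genes are not independent replicates, and these correlations describe the libraries only.

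The comparison of DAP with control asks which genes changed their level in cells labelled as given DAP. The difference between the groups was broad, and mostly small on the scale of log2(FPKM + 1). Of 23485 genes tested, 4069 rose and 3817 fell, together 7886 or 33.6%, at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment). The median log2 fold change was 0.43 among the genes that rose and −0.40 among those that fell. A change of at least 2-fold was found for 384 genes that rose and 207 that fell. This excess of rising genes was seen with the pseudocount of 1 and not with 0.1, which gave 753 that rose and 756 that fell, nor with limma-voom on the recovered counts, which gave 1075 and 1141. Unless another setting is named, log2 fold changes are on the scale of log2(FPKM + 1), which understates the change of genes at low level.

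The identifier with the largest rise under the rule for named genes was MGP_BALBcJ_G0031751, at 63.6 ± 2.27 FPKM (SD, n = 3) in DAP libraries and 1.83 ± 0.0699 FPKM (SD, n = 3) in control libraries. Its log2 fold change was 4.51 (SE 0.0387; adjusted p = 7.93e-07, limma with Benjamini-Hochberg adjustment), and the ratio of the mean FPKM was 34.8. These values rest on 7662 to 9115 recovered counts per DAP library and 244 to 250 per control library. MGP_BALBcJ_G0019898 followed at 87.5 ± 1.63 FPKM (SD, n = 3) under DAP and 5.52 ± 0.530 FPKM (SD, n = 3) in control, a ratio of 15.8. Its recovered counts ran from 6968 to 7545 in DAP libraries and from 432 to 529 in control libraries, and the adjusted p was 5.21e-06 by limma with Benjamini-Hochberg adjustment.

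Among identifiers that fell, MGP_BALBcJ_G0029671 had a log2 fold change of −2.49 (SE 0.0661; adjusted p = 1.14e-05, limma with Benjamini-Hochberg adjustment). Its level was 3.04 ± 0.329 FPKM (SD, n = 3) in DAP libraries and 21.6 ± 0.717 FPKM (SD, n = 3) in control libraries, so the control mean was 7.11 times the DAP mean. MGP_BALBcJ_G0019325 stood at 1.33 ± 0.0447 FPKM (SD, n = 3) under DAP and 11.4 ± 0.536 FPKM (SD, n = 3) in control, and the control mean was 8.56 times the DAP mean. Its log2 fold change was −2.41 (SE 0.0568; adjusted p = 1.13e-05, limma with Benjamini-Hochberg adjustment). The order of these 2 turned with a pseudocount of 0.1, which gave −2.80 for MGP_BALBcJ_G0029671 and −3.00 for MGP_BALBcJ_G0019325, and with limma-voom, which gave −2.83 and −3.09. For each of the 4 identifiers, every DAP library lay on one side of every control library, which the rule for named genes required. Without gene names or positions in the files, what these identifiers encode and where they lie is not given here.

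**Figure D1:**
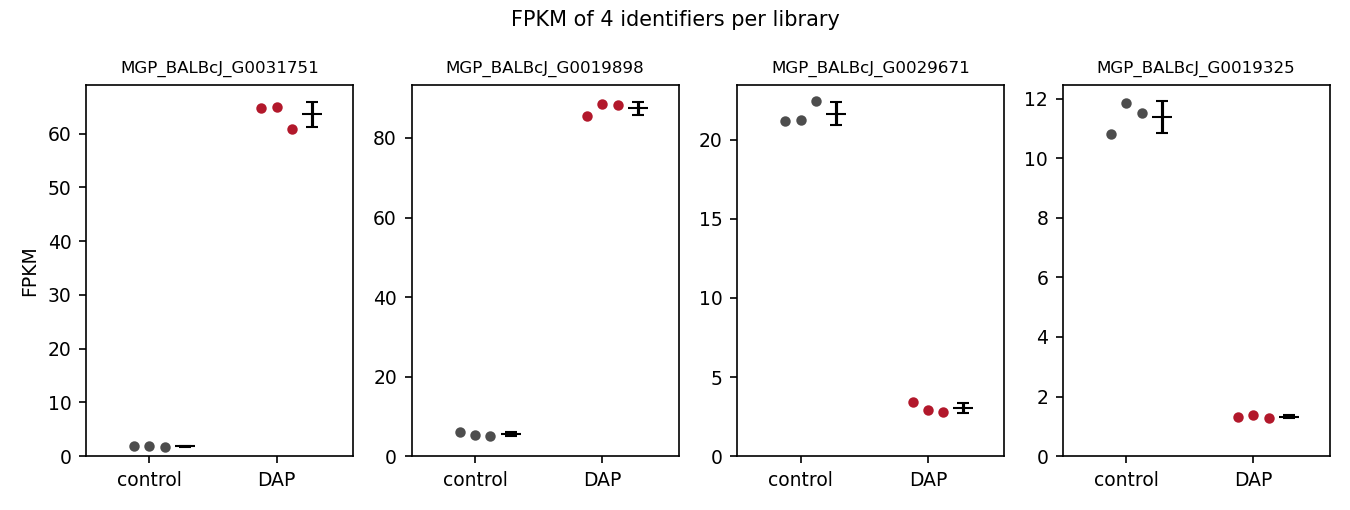
FPKM (linear axes from 0) of the 4 named identifiers in each library, with points for replicates 1, 2 and 3 from left to right, and the mean with its SD (n = 3) beside each group. MGP_BALBcJ_G0031751 and MGP_BALBcJ_G0019898 average 63.6 and 87.5 FPKM in DAP libraries. No DAP library overlaps the control libraries for any of the 4, which the rule for named genes required.

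The share of genes that passed the threshold differed between levels of expression. At low level a pseudocount of 1 shrinks changes, and fewer counts lie behind each value. The shares therefore also reflect how readily a change could be called. Of 11420 genes with a mean under 1 FPKM, 406 rose and 618 fell, or 8.97% in all. Between 1 and 5 FPKM, 640 of 3818 genes rose and 918 fell. Among 2903 genes between 20 and 100 FPKM, 1255 rose and 790 fell, so that 70.4% of the class changed. At 100 FPKM or more, 177 of 455 genes rose and 116 fell, or 64.4% in all. Falling genes outnumbered rising ones under 5 FPKM, and rising genes outnumbered falling ones from 20 FPKM upward, with the deposited scaling, with library size only and with upper-quartile factors. In the class from 5 to 20 FPKM, 1591 of 4889 genes rose and 1375 fell, and this order turned with scaling by library size only, which gave 1389 that rose and 1619 that fell, and with upper-quartile scaling. These classes describe the calls and were not tested against each other.

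**Figure D2:**
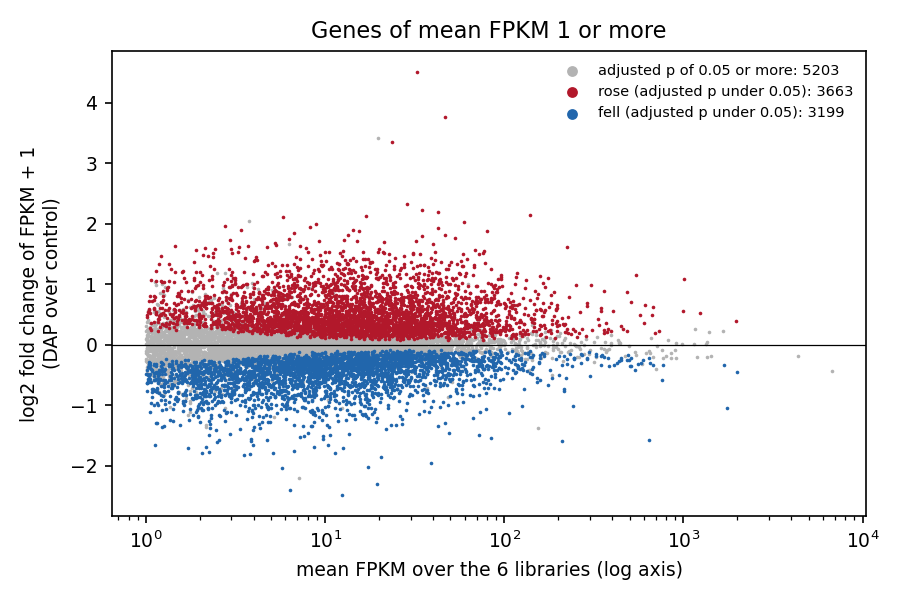
Log2 fold change of FPKM + 1 (DAP over control) against the mean FPKM over the 6 libraries on a log axis, 1 point for each of 12065 genes with a mean of 1 FPKM or more. Of these, 3663 rose, 3199 fell and 5203 did not pass the adjusted p threshold of 0.05 (limma with Benjamini-Hochberg adjustment), and most points lie within a log2 change of 1 either way.

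The loci added to the annotation fell more often than they rose. Of 678 that were tested, 93 rose and 140 fell, against 3976 that rose and 3677 that fell among 22807 annotated genes. The falling share of changed loci was 60.1% for added loci and 48.1% for annotated genes. Under library size scaling these shares were 66.0% and 55.0%, so added loci kept the higher falling share while the majority of annotated genes turned. Added loci held 1.71 ± 0.0174% (SD, n = 3) of recovered counts in DAP libraries and 2.12 ± 0.0131% (SD, n = 3) in control libraries. The groups did not overlap (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). Without the 2 most counted added loci, which were singled out after their values were seen, the share was 0.901 ± 0.00213% (SD, n = 3) in DAP and 0.887 ± 0.00307% (SD, n = 3) in control libraries, so that its direction turned.

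Values above 0 in all 3 DAP libraries and 0 in all 3 control libraries occurred for 92 genes, and the reverse for 103 genes. None of the first set had more than 35 recovered counts over its 3 libraries and none of the second more than 29. These are the smallest whole counts that met the values, and the true ones may be higher. In the first set 41 genes passed the adjusted p threshold and in the second 47 (limma with Benjamini-Hochberg adjustment), in sets chosen for separating the groups. At this depth the data do not show whether such genes were absent in the other group. Choices of 3 libraries that mixed the groups gave 40 to 72 such genes.

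The number of genes that changed by at least 2-fold rests on how low values are treated. It was 591 with a pseudocount of 1, 1509 with 0.1 and 2216 with limma-voom on the recovered counts. The majority direction also depends on scaling. Rising genes made up 51.6% of the changed genes as deposited, but 44.6% with library size only and 46.2% with upper-quartile factors. The p-values measure only the spread between these libraries, which limma moderates by that of other genes at a like level, since the labels speak of pooled RNA from biological replicates and do not make clear whether each library came from its own culture.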

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

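The count of changed genes was 7886. Over 14 of 15 alternatives it stayed between 6690 and 8739, with rising and falling genes within 1.5 times their counts as reported. The test against a 1.2-fold change gave 2992 changed genes, 1682 rising and 1310 falling, which follows from its stricter hypothesis. Genes changed at least 2-fold moved from 591 to 1509 with a pseudocount of 0.1 and to 2216 with limma-voom on recovered counts. Of these, 578, 967 and 1054 had a mean of 1 FPKM or more, so most of the added ones lie at low level, where a pseudocount of 1 shrinks fold changes. Leaving out 1 library at a time gave 6690 to 7331 changed genes, 3493 to 3868 rising, 3141 to 3463 falling and 592 to 602 changed at least 2-fold. Library size only gave 3589 rising and 4452 falling genes, the opposite majority. Median-of-ratios scaling moved almost nothing (7887), since the FPKM already held it. The 4 named identifiers kept their direction and their side of the threshold in all 15 alternatives, with adjusted p (limma or limma-voom, Benjamini-Hochberg) of at most 0.000783. They had been picked for the largest changes in these same libraries, so this is not an independent check of them.

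Whether samples of the same replicate number share more than a number is not settled. Their deviations from the group means correlated at −0.05, 0.06 and 0.08 for numbers 1, 2 and 3. Only numbers 2 and 3 correlated best with their own. On principal component 2 (6.038% of variance, 12065 genes), DAP replicates 1, 2 and 3 scored 3.834, −11.63 and 7.812. Control replicates 1, 2 and 3 scored −0.6203, −7.01 and 7.612, in the same order. With 3 libraries per group, a shared order cannot show a replicate effect. With the replicate block, 7192 genes changed (3765 rising, 3427 falling), 590 of them at least 2-fold, and 6828 were shared with the fit without it. The planned count-model fits and TMM factors were not run; of the tests on counts, only limma-voom was run on the recovered counts. Gene list tests were not run because the identifiers carry no names.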

Other observations

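The tests on the number of values at 2 and at 4, the split of the 10 most counted genes and the check of the SE of the most counted locus were chosen only after the results they bear on were seen.

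Calls among the most abundant transcripts went both ways. Of the 100 genes with the highest mean FPKM, 27 rose, 28 fell and 4 changed at least 2-fold (limma with Benjamini-Hochberg adjustment). Their median log2 fold change was −0.0841, against 0.0156 over all genes with a mean of 1 FPKM or more. Whether the set as a whole moved was not tested. The 10 most counted genes, 2 of them added loci, held 3.20 ± 0.0219% of counts in DAP libraries and 3.77 ± 0.0285% in control libraries (SD, n = 3). Most of this drop lay in the 2 added loci, which held 0.807 ± 0.0195% and 1.23 ± 0.0161%, while the other 8 genes held 2.39 ± 0.0370% and 2.54 ± 0.0127%.

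The breadth of the difference between groups, 7886 changed genes, was set against technical explanations. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was the only 1 to give as many genes, and the highest of the others gave 3. The other splits mix the groups, so the difference between groups adds to the spread within each side and leaves few calls. They do not measure how many genes a split of like libraries would give, and no conclusion is drawn from them. Scaling by library size only or by upper-quartile factors called at least 7976 genes. Thinning all libraries to the lowest total called 7830, and removing each library's trend with gene length called 7968. The recovered totals of the groups overlap, and gene length correlated with log2 fold change at −0.042 (Spearman, 12065 genes). Thinning and trend removal thus had little to remove between the groups. Between 2 libraries of the same group the correlation with gene length reached 0.16 in absolute value, so single libraries did carry a length trend. It is the overlap of the totals and the weak correlation between groups that argue against depth and length as the whole source. A scaling factor moves all genes of a library alike, so the other scalings test the number of calls only weakly. Whether the libraries of a group differ as separate cultures would, and which preparation of DAP was given, stays open. A response of the cells to what the DAP group received is a hypothesis. No test here separates it from a difference between 2 cultures, if the libraries of each group came from pooled RNA.

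The smaller share of counts on added loci under DAP lay in 2 loci, which held 0.807 ± 0.0195% in DAP and 1.23 ± 0.0161% in control libraries (SD, n = 3). The second most counted added locus stood at 1141 ± 15.4 FPKM in DAP and 2361 ± 50.4 FPKM in control libraries (SD, n = 3), and its adjusted p was 0.000318 by limma with Benjamini-Hochberg adjustment. The most counted stood at 4067 ± 121 and 4641 ± 10.6 FPKM without overlap, and did not pass the test (adjusted p = 0.497, limma with Benjamini-Hochberg adjustment). Its SE of 0.183 came mostly from the mean-variance trend at very high level, since its own libraries gave 0.0251, and 3 of 15 alternatives called it (adjusted p from 7.52e-09 to 1 by limma or limma-voom). Both were singled out after their values were seen. Without them the mean share was 0.014 percentage points higher in DAP than in control libraries (0.901% and 0.887%), so the direction turned. Matched in 5 bins of mean FPKM, changed added loci had an odds ratio of 1.41 of falling against changed annotated genes (95% interval 1.05 to 1.89). The more frequent falls of added loci thus remained after this coarse matching on abundance. The interval counts loci as independent, which they need not be, and its lower end lies close to 1. Abundance is therefore not excluded as the source.

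Recovered counts of 2 were more frequent than the mean of counts of 1 and 3 in every library, by a ratio of at least 1.35. In DAP replicate 1 there were 1053 values at 1, 1116 at 2 and 453 at 3. The common factor of a gene's counts is least certain for genes seen in few libraries. Among the 16277 genes above 0 in all libraries the ratio was at least 1.37, as was that of values at 4 to the mean of those at 3 and 5. A candidate explanation is that both mates of a read pair were counted singly, so that a fragment often adds 2. The recovered counts would then overstate the number of independent fragments, and sampling noise computed from them would be too small. No biological explanation was tested for this pattern.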
